A study of Homo sapiens with 6 samples.

How the data were processed

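Total RNA from 3 PC9 and 3 PC9/GR samples was labelled with one dye and hybridised to Agilent arrays, per the labels' protocols. Group and replicate number were taken from the sample titles. The deposited scanner files hold the signal intensity of each of 162814 spots per array, of which 4974 are control spots. Images were extracted with Agilent Feature Extraction, whose version is 12.0.3.2 per the file headers and 10.7 per the submitters' processing notes. The intensities used are the processed signal, which per the file headers had been background-subtracted within the array, and the median spot and local background signals. A deposited table of the whole series holds the authors' log2 values for 154529 probes. The submitters' processing notes name limma, and the normalisation is not given in the sources used here. From the values, each column's rank order equals that of the same array's processed signal, and 100% of values lie within 0.1 of a quantile normalisation of it. The column medians run from 4.569 to 4.582. Columns run in the direction of expression, and no gene centring was seen. Scanner files hold 3311 EX_ probes that have no row in the table used here, and 1009 of these were tested.

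The main setting was log2 of the processed signal minus the array's 75th percentile over non-control probes. The 75th percentile was 146.7 to 161.2 signal units on PC9 arrays and 144.8 to 155.9 on PC9/GR arrays. Values flagged as outliers were left out, which affected 101 probes, and control spots were left out of the tests. Each non-control probe has 1 spot. A probe was tested when it was well above background on all 3 arrays of at least 1 group. The groups were compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, two-sided, on all 6 arrays without covariates, and p-values were adjusted by the Benjamini-Hochberg method over the 97098 tested probes. A probe was called at an adjusted p under 0.05. Control probes named for GAPDH and PGK1 were averaged over their 10 spots and fitted together with the tested probes, a choice made after the data were seen. The spike-in level of an array is the mean log2 signal of the 6 E1A probes whose median signal lay between 100 and 100000 on every array. E1A probes measure a control RNA that is added to each labelling reaction in the usual form of this assay; its addition is not described in the labels.

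The fit was tested on simulated data made from the means and spreads of 97027 of these probes. Values were drawn independently from normal distributions, with the same spread in both groups and no slide effect. The false calls given here are therefore no error rate for the real arrays. With 200 changed probes it recovered 16% of the 2-fold and 65% of the 4-fold changes, with 2 false calls. With 20000 changed probes it recovered 81.1% of the 2-fold and 95.5% of the 4-fold changes, with 785 false calls. The median estimated changes were 1.00 and 2.00 log2 units for simulated changes of 1 and 2.

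Slides were read from the names of the scanner files. Slide A holds only PC9 arrays, so its effect can be separated from the group only through PC9 replicate 3.

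Before the data were examined, the tests, the rule for named genes, 34 gene lists, a list of circRNAs and the alternative settings were fixed. The counts by mRNA, lncRNA and circRNA, the share called per class, the gene lists and the comparison of circRNAs with host genes were not run. In the scanner files the systematic name of every non-control probe repeats its probe ID, and 0 of the IDs matched the gene table used here. Probes are therefore described by ID, with coordinates left out. The rule named, among called probes whose groups do not overlap, the 10 largest rises and 10 largest falls of mRNAs well above background on all 6 arrays, 5 of each among lncRNAs and among circRNAs, 3 mRNAs per direction detected in 1 group only, up to 4 members per gene list, up to 3 listed circRNAs, and a fixed set of genes of EGFR signalling, drug efflux, epithelial state and apoptosis. Without gene names only its first part was applied, over all probes, and limited to 2 IDs in each direction. The GAPDH and PGK1 control probes and the E1A probes lie outside that rule and were chosen after their values were seen. The sets of A_ and EX_ probes were defined after the probe IDs were seen.

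The alternatives were quantile and median normalisation, normexp background correction (offset 50) with quantile normalisation, no filter or a stricter filter on dim probes, slide as a fixed or random block, slide B alone, the replicate number as a block, the authors' log2 values, another variance model, and leaving out each sample. Normexp used the median spot signal in place of the mean. Scaling to the spike-ins and cyclic loess were added after seeing the data.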

Results

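PC9 is a human lung adenocarcinoma cell line whose growth depends on the EGFR receptor and which is killed by gefitinib, an inhibitor of that receptor's kinase. PC9/GR is a clone derived from PC9 by raising gefitinib stepwise from 8 to 100 nM, and it was obtained after 6 months of exposure. Total RNA of both was measured on one-colour Agilent arrays, with 3 PC9 samples and 3 PC9/GR samples and 1 array per sample. No label says whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. On the PC9 arrays 62.8 to 64.5% of probes were well above background, and on the PC9/GR arrays 60.9 to 62.6%. No spot was saturated on any array. The number of arrays limits the precision. PC9 replicates 1 and 2 lay on one slide, called slide A here, and PC9 replicate 3 lay with all PC9/GR arrays on another, slide B.

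The series was set up to find lncRNAs, circRNAs and mRNAs linked to gefitinib resistance in PC9 cells. The probes were identified in the files used here only by probe ID, so none of the non-control probes could be given a gene or an RNA class. Results are therefore given for all probes and for 2 sets defined by the start of the ID. The 25353 probes whose ID starts with A_ are called A_ probes and the 132487 others, whose ID starts with EX_, EX_ probes; the meaning of these starts is not given in the sources used here. GAPDH and PGK1, the genes named in the files, are measured by control probes and are described separately.

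PC9/GR differed from PC9 at a large share of the probes tested. PC9/GR is a single clone, so changes linked to resistance cannot be told apart from other differences between it and its parental line. Of 97098 probes well above background on all 3 arrays of at least 1 group, 23328 were higher and 18018 lower in PC9/GR (limma, Benjamini-Hochberg adjusted p under 0.05). These 41346 probes were 42.6% of those tested. A change of at least 2-fold was called for 10157 higher and 7175 lower probes, and one of at least 8-fold, among probes well above background on all 6 arrays, for 356 higher and 177 lower probes. With normexp background correction and quantile normalisation the 2-fold counts were 3451 higher and 2456 lower. The median SD between replicate arrays was 0.231 log2 units in PC9, 0.139 for PC9 replicates 1 and 2 alone, and 0.0957 in PC9/GR. In 54746 of the tested probes, or 56.4%, the PC9/GR values lay wholly above or wholly below the PC9 values. Chance gives 10% where all 6 arrays are exchangeable. A slide effect can raise that chance share, since the groups lie unevenly on the slides.

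These counts changed with the handling of the slide and when PC9 replicate 3 was left out. For that array an effect of the slide and one of the sample cannot be told apart. With slide as a fixed block 24206 probes were called higher and 19716 lower, and on slide B alone, where PC9 replicate 3 is the only PC9 array and is assumed to vary like the PC9/GR arrays, 27918 and 21874. Of the 41346 calls, 33358 were also made in the same direction with the block. Since slide A holds only PC9 arrays, the block too estimates each change from PC9/GR against PC9 replicate 3 alone. The block and slide B alone are thus not separate checks. Without PC9 replicate 3 all PC9 arrays lay on slide A and all PC9/GR arrays on slide B, so group and slide cannot be told apart. In that setting the probes called at least 2-fold lower rose to 12113. All called lower rose to 29624 against 28743 called higher, so that 49.2% of calls and 46.6% of 2-fold calls were higher. Called lower probes numbered 12003 without PC9/GR replicate 2 and 11982 without PC9/GR replicate 3. Against PC9 on each slide separately, 8164 called probes were at least 2-fold higher and 5312 at least 2-fold lower in PC9/GR. The split between higher and lower calls thus turned without PC9 replicate 3, and it also depended on the scaling. Scaling to the 75th percentile of each array gave 56.4% of calls as higher, and scaling to the E1A spike-in probes gave 25.3%, with the median change of all tested probes at -0.01 and -0.38 log2 units. The spike-in scaling was added after seeing the data.

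**Figure D1:**
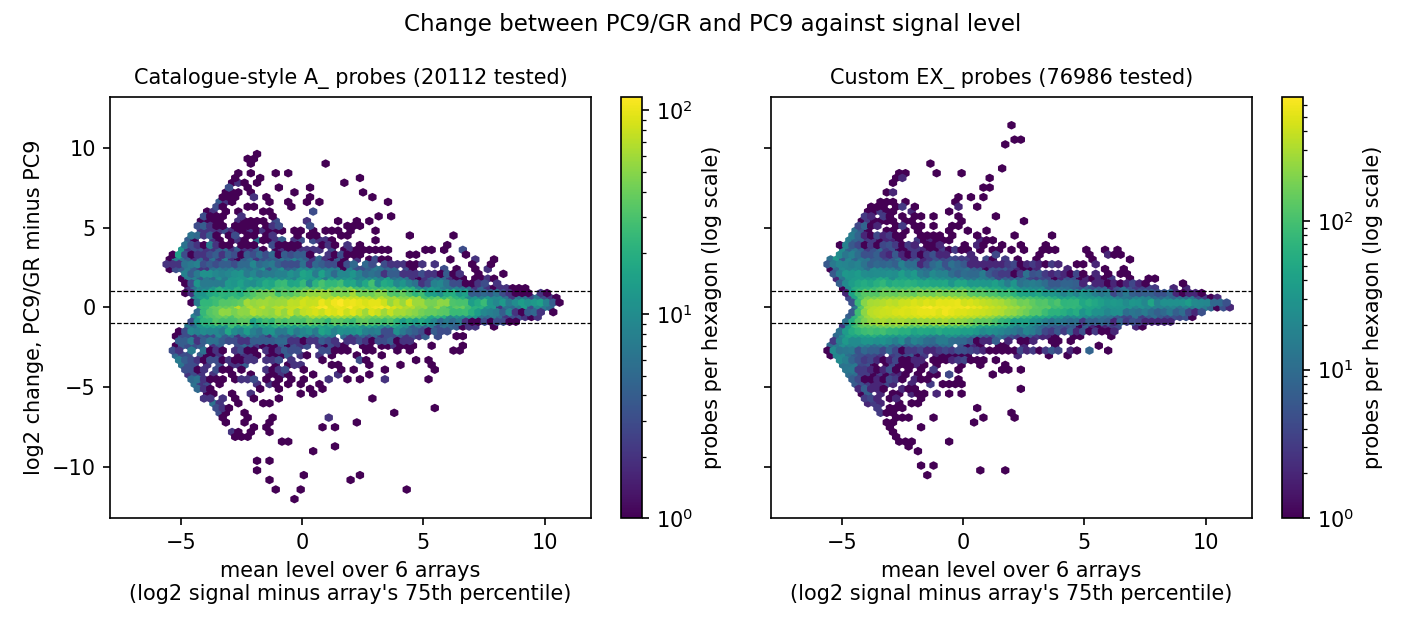
Log2 change (PC9/GR minus PC9) of each tested probe against its mean level over the 6 arrays, for 20112 A_ probes and 76986 EX_ probes; colour gives the number of probes per hexagon on a log scale and dashed lines mark 2-fold changes. Changes of over 10 log2 units in both directions lie apart from the bulk of probes, whose median change is 0.12 in the A_ set and -0.038 in the EX_ set.

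The largest changes measured on both sides of the comparison were of over 10 log2 units. Probe A_32_P33083 fell by 11.23 log2 units in PC9/GR (SE 0.24, limma adjusted p = 3.61e-06), from a scaled level of 9.89 ± 0.19 (SD, n = 3) to -1.33 ± 0.44. Its unscaled signal lay between 134372 and 167284 on the PC9 arrays and between 49.2 and 88 on the PC9/GR arrays. Probe A_24_P230282 fell by 10.86 (SE 0.13, limma adjusted p = 1.62e-06). Probe EX_27_5002606 rose by 11.36 (SE 0.21, limma adjusted p = 2.57e-06), from a signal between 9.62 and 14.5 to one between 26603 and 29844. Probe EX_08_0479763 rose by 10.58 (SE 0.49, limma adjusted p = 4.14e-05). Against PC9 replicate 3 alone, on the shared slide, the changes of these probes were -11.41, -10.72, 11.58 and 11.70 in the same order. With normexp and quantile normalisation they were -10.39, -8.65, 8.72 and 8.44. Of the 10 largest falls 8 were A_ probes, and of the 10 largest rises 7 were EX_ probes. The 88082 probes well above background on all 6 arrays, among which these were ranked, held 18704 A_ and 69378 EX_ probes. The EX_ share of the rises was thus not larger than their share of the probes, while the A_ share of the falls was larger than theirs. Among these ranked probes the A_ probes were brighter, with a median scaled level of 1.4 against -0.694 log2 units.

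Some probes were well above background in one line only. In PC9/GR 1392 probes were well above background on all 3 arrays while not well above it on any PC9 array, and 1353 of these were called higher. In PC9 the converse held for 1778 probes, of which 1535 were called lower. Because the dim group gives only a bound, each fold was set against the higher of the probe's own signal and the lowest signal among probes well above background on the same array. On that basis 952 probes were at least 2-fold and 179 at least 8-fold higher in PC9/GR, the largest at least 292-fold. Conversely 897 were at least 2-fold and 166 at least 8-fold higher in PC9, the largest at least 1258-fold. On slide B alone, where fewer arrays have to meet the condition, the counts were 2408 probes in PC9/GR only and 4340 in PC9 only. Without PC9 replicate 3 they were 2160 and 4645. There too fewer arrays have to meet the condition, and group and slide cannot be told apart.

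The A_ and EX_ probe sets both held many changed members. Among 20112 tested A_ probes 6526 were called higher and 3710 lower, which is 50.9% called and 63.8% of calls higher. Among 76986 tested EX_ probes 16802 were called higher and 14308 lower, which is 40.4% called and 54% of calls higher. The A_ probes were brighter, with a median scaled level of 1.1 against -0.99 log2 units. In each of 5 bins of brightness the called share was larger among A_ probes, with 49.6% against 37.8% in the dimmest bin and 50.7% against 43.6% in the brightest. On slide B alone 58.4% of called A_ probes and 55.3% of called EX_ probes were higher. With spike-in scaling these shares were 36.6% and 22%. Without PC9 replicate 3, where group and slide cannot be told apart, they were 61% and 45.9%. There 20852 EX_ probes were called higher and 24589 lower. Among probes well above background on all 6 arrays, changes of at least 8-fold were called for 220 higher and 99 lower A_ probes, and for 136 higher and 78 lower EX_ probes. Probes of one gene are not independent, so the difference between the sets was not tested.

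GAPDH and PGK1 encode enzymes of glycolysis, and the distance between their levels was larger in PC9/GR. Each is measured by a pair of human control probes, named with the endings _3 and _5, on 10 spots per array. Human-GAPDH_5 rose by 0.65 log2 units in PC9/GR, a 1.57-fold change (SE 0.10, limma adjusted p = 0.00333). With slide as a block, where the change rests on PC9 replicate 3 as the only PC9 array, it rose by 0.59. With spike-in scaling and no block the Human-GAPDH_5 change was 0.28 with a limma adjusted p of 0.0908. Human-GAPDH_3 differed by 0.36 (SE 0.12, limma adjusted p = 0.057), by 0.20 with slide as a block and by -0.01 with spike-in scaling (limma adjusted p = 0.932). Human-PGK1_3 differed by -0.17 (SE 0.12, limma adjusted p = 0.284) and Human-PGK1_5 by -0.22 (SE 0.11, limma adjusted p = 0.173). With spike-in scaling these were -0.54 and -0.59, at limma adjusted p of 0.0103 and 0.00614.

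The distance between the GAPDH and PGK1 levels within an array is the same under 75th percentile and spike-in scaling. It was larger in PC9/GR by 0.53 log2 units for the _3 probes (SD 0.05 in PC9 and 0.04 in PC9/GR, n = 3 each) and by 0.87 for the _5 probes (SD 0.03 and 0.09). On slide B alone the differences were 0.47 and 0.85. The exact two-sided permutation p was 0.1 for each, the smallest that 3 arrays against 3 can give.

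**Figure D2:**
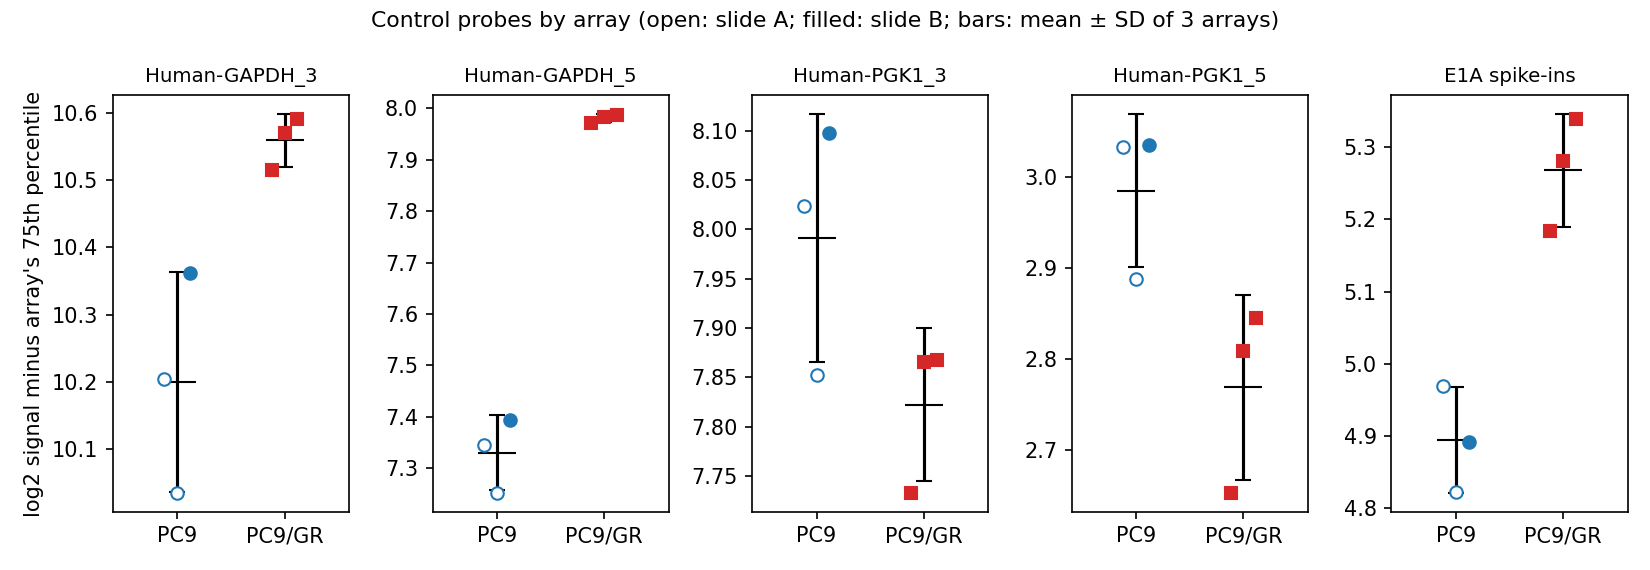
Scaled log2 signal of the human GAPDH and PGK1 control probes and of 6 E1A spike-in probes on each array (points; open symbols slide A, filled symbols slide B), with the mean ± SD of 3 arrays per group; each panel has its own axis, which does not start at 0. All PC9/GR arrays lie above all PC9 arrays for both GAPDH probes and for the spike-ins, while with spike-in scaling the Human-GAPDH_3 change is -0.01.

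PC9 replicate 3 stood apart from the other PC9 arrays. Its correlation over the 88082 probes well above background on all 6 arrays was 0.972 with replicate 1 and 0.9737 with replicate 2, which correlated with each other at 0.9918. It correlated at 0.9448 to 0.9494 with the PC9/GR arrays, which correlated with each other at 0.9947 to 0.9966. Of those 88082 probes, 8104, or 9.2%, were at least 2-fold lower in PC9 replicate 3 than in the mean of replicates 1 and 2, and 319 were at least 2-fold higher. These counts were 5607 and 1525 with quantile normalisation, and 1482 and 43 with normexp followed by quantile normalisation. The median unscaled signal was 19.19 on PC9 replicate 3, 24.31 and 26.67 on replicates 1 and 2, and 21.05 to 22.57 on the PC9/GR arrays. The 75th percentile of PC9 replicate 3, 155.3, lay between the 146.7 and 161.2 of replicates 1 and 2. The lower probes had a median signal of 59 in replicates 1 and 2, 19.8 in replicate 3 and 27.2 in PC9/GR, and 88.4% of them were EX_ probes. Their median change from the slide A arrays to PC9 replicate 3 was -1.42 log2 units, and their median difference between PC9/GR and PC9 replicate 3 was 0.41. Of the 8104 probes, which were picked for their spread within PC9, 269 were called lower and 201 higher in PC9/GR than in PC9. Over all 97098 tested probes, 5706 were called at least 2-fold lower in PC9/GR without PC9 replicate 3 but not with it. Of these, 5071, or 88.9%, were at least 2-fold lower in PC9 replicate 3 than in PC9 replicates 1 and 2. Among all tested probes 10505 were that low. The selection itself favours probes that are low in PC9 replicate 3, so the share is not separate evidence.

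**Figure D3:**
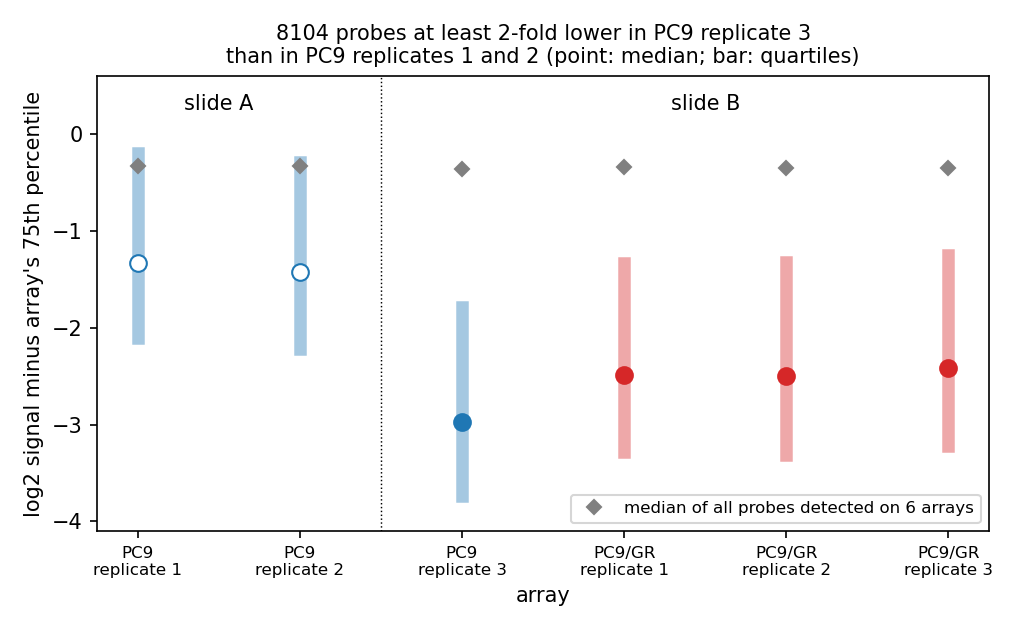
Scaled log2 signal on each array, as median (point) and quartiles (bar), of the 8104 probes at least 2-fold lower in PC9 replicate 3 than in PC9 replicates 1 and 2; diamonds give the median of all 88082 probes detected on 6 arrays. The medians are -1.33 and -1.43 on slide A and lie between -2.97 and -2.42 on slide B, where the PC9/GR arrays lie.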

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

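The tests on the slide, the control probes of other species, the sample swap and the spike-in probes, and the cyclic loess normalisation, were chosen only after related results were seen.

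The first pattern is the set of 8104 probes at least 2-fold lower in PC9 replicate 3 than in PC9 replicates 1 and 2. With quantile normalisation 5607 probes were that low, so the size of the set depends on the scaling. A swap with a PC9/GR sample is argued against, since the mean correlation of PC9 replicate 3 with PC9/GR minus that with PC9 was -0.0255. An effect of the slide or hybridisation may account for it, since the median of PC9/GR minus PC9 replicate 3 on these probes was 0.41 log2 units on the shared slide, against a median change of -1.42 from slide A. More cross-hybridisation on slide A stays open. It was examined with 13 control probes of ERCC, ETG, mouse or rat name that had a signal of at least 10 there. Of these, 6 fell at least 2-fold on PC9 replicate 3, and the median change was -0.97. The 4 that lay between -0.01 and 0.10 were mouse and rat GAPDH and PGK1 probes. Every ERCC and ETG probe among the 13 was lower, with changes of -0.65 to -3.06. On the PC9/GR arrays these probes were lower too. Their unscaled signals were 17.2, 29.2, 398, 35.7, 19.7 and 20.5 on slide A. In the same order they were 8.41, 7.04, 265, 30.4, 13.6 and 6.88 in PC9/GR. They were picked for their signal on slide A, which favours lower values elsewhere. The mouse and rat probes may read human GAPDH and PGK1 RNA, which was not tested, so they cannot decide the question. A difference of the culture behind PC9 replicate 3, or of its RNA preparation, stays open as untested.

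The second pattern is that more called A_ probes were higher than lower in PC9/GR. In bins of equal brightness 59.6 to 65.2% of called A_ probes were higher, against 51.7 to 61% of called EX_ probes. In the brightest bin, which held 8502 A_ probes, the shares were 63.8% and 61%. From the dimmest to the brightest bin the median change went from -0.03 to 0.14 for A_ and from -0.18 to 0.092 for EX_ probes. The bins alone cannot exclude a scaling that depends on brightness, since the sets may differ for other reasons within a bin. That cause stays open. After cyclic loess the share of called A_ probes that were higher fell to 59.5%. That lies between the bounds set for and against it, just below the bound set against it. The slide stays open in the same way, with a share of 58.4% on slide B alone, as does, untested, a difference between the resistant clone and its parental line. With spike-in scaling the share was 36.6%, so the direction itself depends on the scaling.

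The third pattern is the E1A spike-in level, a signal in data outside the comparison of probes. Relative to the 75th percentile it was higher in PC9/GR by 0.37 log2 units (SD 0.073 in PC9 and 0.078 in PC9/GR, n = 3 each; exact two-sided permutation p = 0.1, the smallest possible), with all PC9/GR arrays above all PC9 arrays. The slide is argued against, since the unscaled level was 0.33 higher in PC9/GR than in PC9 replicate 3 on the shared slide. The amount of spike-in added and the amount of labelled RNA in each reaction, of technical or biological origin, stay open as untested. If the control RNA was added to the labelling reaction, as is usual, its level gives no measure of RNA per cell.

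Mouse-GAPDH_3 and Rat-GAPDH_5, control probes that the comparison of human probes leaves out, were higher in PC9/GR by 0.67 log2 units (limma adjusted p = 0.00266; 0.30 with a limma adjusted p of 0.0741 under spike-in scaling) and by 0.77 (limma adjusted p = 0.00161; 0.39 with a limma adjusted p of 0.029 under spike-in scaling), with all 3 PC9/GR arrays above all 3 PC9 arrays. The other rodent GAPDH probes, dimmer, differed by -0.60 (Mouse-GAPDH_5, limma adjusted p = 0.298) and -0.41 (Rat-GAPDH_3, limma adjusted p = 0.0592). Whether rodent probes read human GAPDH RNA was not tested, so these values are not a signal apart from the human GAPDH probes.

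The split of the 6 samples into PC9 and PC9/GR called 41346 probes, of which 10236 were A_ probes, 31110 were EX_ probes and 17332 changed at least 2-fold. The highest of the other splits into 3 and 3 called 0 in each case, so 1 of 10 splits gave as many. Besides, 10 splits are too few for a share under 0.05. Each other split mixes PC9 and PC9/GR arrays in both groups, so the difference between the lines adds to the spread within groups. Few calls were bound to result, and the counts of 0 do not show how many calls chance would give.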

How the results depend on the processing

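The tests with spike-in scaling and cyclic loess and those on control probes were chosen only after results were seen, and counts by ID start and of probes detected in 1 group were added later. The count of all called probes stayed within 1.5 times of 41346 under each alternative, from 28553 to 58367 with 1 sample left out. With 1 sample left out, higher calls ran from 16571 to 28743, lower calls from 11982 to 29624, 2-fold higher calls from 9497 to 10579 and 2-fold lower calls from 6519 to 12113. For A_ probes the ranges were 4991 to 7891 higher and 2540 to 5035 lower, and for EX_ probes 11580 to 20852 higher and 9414 to 24589 lower. Probes detected in PC9/GR only ran from 1515 to 2160 and in PC9 only from 2001 to 4645, against 1392 and 1778 on all arrays. On slide B alone they were 2408 and 4340. In each of these settings fewer arrays must meet the condition, so the counts can only rise. Every highest value with 1 sample left out came without PC9 replicate 3, where group and slide cannot be told apart. With spike-in scaling 12044 probes were higher and 35573 lower, 5882 and 16487 of them at least 2-fold; A_ probes gave 3920 and 6796, and EX_ probes 8124 and 28777. That scaling shifted all changes down and turned Human-GAPDH_3 to -0.01. Normexp with quantile normalisation gave 3451 higher and 2456 lower 2-fold calls. It gave 1482 lower and 43 higher probes in PC9 replicate 3 against the other PC9 arrays. Its offset shrinks the changes of dim probes. That setting also changed the spot signal used and the normalisation, so the moves cannot be put down to the offset alone. The probes higher in PC9 replicate 3 numbered 1525 with quantile normalisation and 1502 with the authors' values; the cause was not tested.

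The difference between GAPDH and PGK1 changes kept its sign under each alternative run, with 0.76 under quantile normalisation and 0.74 under normexp for the _5 probes. Human-PGK1_3 passed the threshold under quantile normalisation (-0.38, limma adjusted p = 0.0265) and normexp (-0.39, limma adjusted p = 0.00262), as did Human-PGK1_5 under normexp (-0.32, limma adjusted p = 0.0118). Human-GAPDH_3 passed it with the other variance model, and without PC9 replicate 3, where group and slide cannot be told apart. The samples share only a replicate number. The correlations of the deviations of same-numbered samples were -0.012, -0.064 and -0.134, and 0 of 3 PC9/GR samples correlated best with the PC9 sample of their number. With the replicate block 33800 probes were called. Alternatives for RNA classes, gene lists and circRNA hosts, and the mean over a gene's probes, were not run for want of gene names. From 60.9 to 64.5% of probes per array were well above background.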
